A study of Escherichia coli with 6 samples.

How the data were processed

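RNA was measured by sequencing in a pair of otherwise isogenic Escherichia coli K-12 strains derived from MG1655, one with the wild-type dnaN gene (dnaN+) and one with the missense allele dnaN-E202K. dnaN encodes the sliding clamp (beta clamp) that holds DNA polymerases on the template. Per the labels' protocols, both strains were grown in Luria-Bertani medium at 37 degrees with aeration to exponential phase, RNA was extracted with phenol and chloroform, ribosomal RNA was removed with a Ribo-Zero bacterial kit, and libraries were made by Illumina protocols. The labels list 6 samples, 3 of each strain.

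The values analysed were FPKM (fragments per transcript length in kilobases, scaled to the number of mapped fragments), which the authors deposited as a single table with 1 value per gene and strain. The first header line names the columns WT and E202K, and these were taken as dnaN+ and dnaN-E202K. Per the submitters' processing notes, the tools included bcl2fastq, TopHat2 2.1.0 and Cufflinks 2.2.1; their order and settings, the genome build and the gene annotation are not given in the sources used here. The file headers carry the names value_1 and value_2 and do not say how the 3 samples of a strain were combined. The column sums differed, at 2486929 FPKM in dnaN+ and 3030867 in dnaN-E202K, whereas the medians were 33.0 and 32.9. The sum of FPKM times gene length in kilobases was 1054248 in dnaN+ and 1248358 in dnaN-E202K, so the columns were not on a scale that gives both strains the same total. The values of any one gene therefore compare the strains only up to a common factor, and 2 alternatives below set that factor differently.

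The table held 4514 rows. The 1 row that names no gene had the value 0 in both strains and was left out, which leaves 4513, of which 4410 are named by gene and 103 by transcript. Locus tags were matched to symbols in a RefSeq gene table of the MG1655 assembly ASM584v2, and 4504 matched. Because the build behind the deposited values is not given, that table served for names, gene lengths, RNA classes and the order of genes along the chromosome, and no coordinates are reported. For 19 locus tags the table has a gene row and a transcript row; the gene row was used, and the transcript row was kept under its own identifier. In all, 265 genes were listed at 0 in both strains, among them all 86 tRNA genes and 115 protein-coding genes. A 0 in this table can be a failed or suppressed estimate and was not read as absence of the transcript.

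No sequencing depth can be given. In low values multiplied by gene length, the best of 400 trial steps made 26.2% of 130 values in dnaN+ and 28.7% of 122 values in dnaN-E202K whole multiples within a tolerance of 0.1, where 20% is expected with no steps, so whole reads could not be recovered. Without depth or replicate values no interval, standard error or p-value applies to any gene. The plan fixed before the data were examined had a replicated linear model for this comparison and a separate rule for a table with 1 value per strain; the latter was used. Genes under 300 nt carried 56.2% of the FPKM sum in dnaN+ and 55.5% in dnaN-E202K.

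Log2 ratios were computed as log2 of (FPKM + 1) in dnaN-E202K over (FPKM + 1) in dnaN+, which understates the ratio of low genes, and folds are on the same scale. The count of genes at least 2-fold apart took those at 10 FPKM or more in either strain. Medians, lists and trends took genes with a mean of at least 1 FPKM. The text names dnaN, dnaA, nrdA, nrdB and hda; the 12 genes with the largest positive and the 12 with the largest negative log2 ratio at 10 FPKM or more, without ribosomal RNA, tRNA and genes under 150 nt; and up to 4 members of each list. That rule was fixed before the data were examined, except that list members were taken by the size of the log2 ratio because no p-value exists. A few genes beside these are named as operon partners or as members that complete a count, and were chosen after their values were seen.

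The 27 gene lists were also fixed before the data were examined. Each list with at least 3 measured genes was described by the percentile of its median log2 ratio among the medians of 10000 random lists of the same size, matched on mean FPKM in 10 bins. A list was called outside the random range when it lay among the lowest or highest 2.5% of random medians, a limit set after the data were examined. A further 6 lists were compiled after the data were examined and are described only after the main results. The percentile describes these 2 columns; genes of one operon are not independent, and it is not a p-value. Distance from the replication origin oriC was counted in genes, from the gap between mnmG and mioC the short way round the circular chromosome, and its rank correlation with the log2 ratio was compared with 10000 circular shifts of the ratios.

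The statistics were tested on simulated values for 4218 genes. Of 200 genes given a 4-fold change, 100% were recovered as at least 2-fold apart, and 0.11% of unchanged genes were counted with them. Of 200 lists of 30 unchanged genes, 4% fell outside the random range, and of 50 lists raised by 0.3 log2 units 86% lay above it. The simulated genes had independent random log2 ratios with an SD of 0.3. The deposited ratios had an SD of 0.68, and neighbouring genes had like ratios. These rates therefore check the computation and do not give the share of false calls in the deposited data. A planted trend along the chromosome was exceeded by 4.02% of shifts, so the shift comparison reacts weakly to smooth trends.

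The results were recomputed, as fixed before the data were examined, with pseudocounts of 0.1 and 5 FPKM, no filter and a filter at a mean of 10 FPKM, scaling to the same median, quantile normalization, and rescaling to the same sum without ribosomal RNA, tRNA and other stable RNA. Alternatives chosen after seeing the data were leaving out genes under 300 nt, scaling to the same sum of FPKM times length, and moving each list along the gene order. Analyses used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.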

Results

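Transcript levels were compared between exponentially growing cultures of Escherichia coli with the wild-type sliding clamp gene dnaN and an isogenic strain with dnaN-E202K, to find which genes differ when the clamp carries this substitution. Each strain had 3 sequenced samples, and the deposited table gives 1 FPKM value per gene for each strain. Of 4513 features, 4016 reached 1 FPKM in dnaN+ and 4007 in dnaN-E202K. The most abundant coding transcripts were the ribosomal protein gene rpmJ, with 258951 FPKM in dnaN+ and 364905 in dnaN-E202K, the cold shock gene cspA, with 154451 and 147415, and the lipoprotein gene lpp, with 74285 and 91074. Because replicate values are not separate, no difference below could be set against the spread between samples, and each is stated as the size of the gap between the 2 deposited values. Read depth is unknown, which leaves counting error open as well.

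Leaving out ribosomal RNA, tRNA and genes under 150 nt, nitrate respiration genes and the autotransporter gene flu stood highest in dnaN-E202K against dnaN+. Genes for the use of lactate, proline, acetate and galactose were among the lowest. Among the 3042 genes at 10 FPKM or more in either strain, 76 were at least 2-fold higher in dnaN-E202K and 108 at least 2-fold lower. Of these, 10 of the higher genes were listed at 0 in dnaN+ and 6 of the lower genes at 0 in dnaN-E202K. Leaving those out, 2 genes were at least 4-fold higher and 28 at least 4-fold lower. The median log2 ratio of 4035 genes with a mean of at least 1 FPKM was 0.03, with quartiles of -0.23 and 0.29, and 53.5% of these genes were higher in dnaN-E202K. The split depended on scale. With both strains set to the same sum of FPKM without stable RNA the median moved by -0.29 and the counts became 25 higher and 198 lower, so the share of higher genes among those 2-fold apart went from 41.3% to 11.2%. With the same sum of FPKM times length, the median moved by -0.23 and the counts were 37 and 176.

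The 12 genes with the largest higher values included a cluster at flu, which encodes the phase-variable surface protein antigen 43. The flu gene had 19.0 FPKM in dnaN+ and 98.3 in dnaN-E202K, a 4.98-fold gap, its neighbour yeeR was 3.74-fold higher, and the small RNA gene isrC, which lies in the same region, was 2.92-fold higher. The nitrate reductase genes narG and narH were 3.89-fold and 2.82-fold higher, and narK, a nitrate and nitrite transporter gene, was 3.74-fold higher. The neighbours rluA, a pseudouridine synthase gene, and rapA, which encodes an RNA polymerase recycling factor, were 2.96-fold and 2.85-fold higher. The next gene along, polB, had a log2 ratio of 0.18. The pyruvate dehydrogenase gene aceE went from 1098 to 3018 FPKM, or 2.75-fold. The genes ycfJ, yjgZ and yjjZ completed the group, at 3.19-fold, 3.05-fold and 2.77-fold.

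Of the 12 genes with the largest lower values, ybfI and ydfW were listed at 0 in dnaN-E202K, with 15.3 and 13.1 FPKM in dnaN+, and no fold is given for them. All 3 genes of the lactate utilisation operon were far lower: lldR was 10.6-fold lower, at 225.9 FPKM in dnaN+ and 20.4 in dnaN-E202K, lldD was 9.01-fold lower and lldP 8.68-fold lower. The proline catabolism gene putA was 9.07-fold lower, the acetyl-CoA synthetase gene acs was 8.46-fold lower and mglC, of the galactose transporter, was 7.70-fold lower. The ydh operon genes ydhV, ydhY and ydhW were 8.08-fold, 7.83-fold and 7.25-fold lower. The small toxin gene hokC went from 43.7 to 4.16 FPKM, an 8.66-fold gap; it is a short member of a family of similar loci, so its value is uncertain.

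The mutated gene itself, dnaN (b3701), had 163.3 FPKM in dnaN+ and 214.4 in dnaN-E202K, a log2 ratio of 0.39 that lay at the 82.3 percentile of all genes. The allele is a missense change, so the dnaN level does not check the strain labels. The replication initiator gene dnaA had 178.1 and 216.4 FPKM (log2 ratio 0.28), and hda, which encodes the clamp-bound regulator of DnaA, had 72.1 and 86.2 (log2 ratio 0.25). Rescaling to the same sum without stable RNA lowered the dnaN ratio to a small positive value, given below. It turned the ratios of dnaA and hda to -0.03 and -0.05. In the list of the dnaA-dnaN operon and its neighbours, 4 of 6 genes were higher and the median log2 ratio was 0.34, at the 89.9 percentile of random lists of like expression. Rescaling without stable RNA gave 3 of 6 higher and a median of 0.03, and quantile normalization gave 3 of 6 and a median of 0.11 at the 70.5 percentile. Its largest ratio was that of rnpA, which encodes the protein part of ribonuclease P, with 957.4 and 1796 FPKM. Next came rpmH, a ribosomal protein gene, at 1.44-fold higher.

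The aerobic ribonucleotide reductase operon was higher in dnaN-E202K, while the genes of the alternative reductase NrdEF were lower. This enzyme class makes deoxyribonucleotides for DNA synthesis. The large subunit gene nrdA (b2234) had 146.0 FPKM in dnaN+ and 369.7 in dnaN-E202K, 2.52-fold higher, and the small subunit gene nrdB (b2235) had 129.7 and 292.8, 2.25-fold higher. The third gene of the operon, yfaE, which encodes a ferredoxin, was 2.05-fold higher. The ratios of nrdA and nrdB lay at the 99.2 and 98.7 percentiles of all genes. Under rescaling without stable RNA the log2 ratio of nrdA was 1.03 and that of nrdB was 0.86, under 2-fold. In the nrdHIEF operon, nrdH had 23.2 and 7.65 FPKM, nrdI 11.7 and 7.38, nrdE 6.36 and 2.57, and nrdF 8.26 and 2.66. The anaerobic genes nrdD and nrdG had log2 ratios of 0.14 and 0.24, and the repressor gene nrdR 0.09. With 3 members at least 2-fold higher and 3 at least 2-fold lower, the median of the 10 reductase genes was 0.12, or -0.19 after that rescaling, at the 73.5 percentile.

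**Figure D1:**
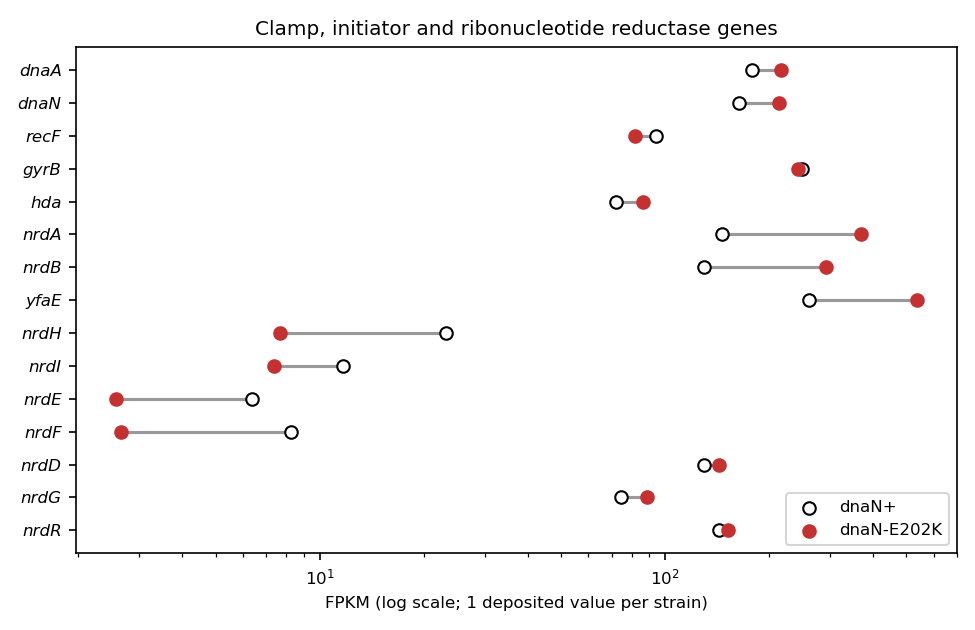
FPKM of clamp, initiator and ribonucleotide reductase genes on a log axis, with open circles for dnaN+ and filled circles for dnaN-E202K, 1 deposited value each. The nrdA, nrdB and yfaE values lie to the right in dnaN-E202K, and nrdH, nrdI, nrdE and nrdF to the left.

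Among the 26 lists large enough to rank, 6 medians lay above the range of random lists and 3 below it. By chance 1.3 would fall outside if the genes within a list were independent, which genes of one operon are not. Among the 6 were the lists of DNA polymerase III holoenzyme, purine biosynthesis and pyrimidine biosynthesis genes. DNA polymerase III holoenzyme genes had a median log2 ratio of 0.37 at the 98.3 percentile, with 8 of 9 members higher and none 2-fold apart. The largest was holD, at 1.48-fold, then holB and dnaN at 1.36-fold and 1.31-fold, and dnaX at 1.31-fold. Without genes under 300 nt its percentile was 96.0, inside the random range. Purine biosynthesis genes had a median of 0.37 at the 99.9 percentile, with 16 of 17 higher. In that list purB was 1.98-fold, guaB 1.62-fold, guaA 1.49-fold and purA 1.48-fold higher. Pyrimidine biosynthesis genes had a median of 0.39 at the 99.8 percentile, with 15 of 17 higher. Their largest ratios were those of pyrF (1.74-fold), pyrD (1.62-fold) and pyrG (1.61-fold), while carA was 1.62-fold lower. After rescaling without stable RNA 5 of 9 polymerase III, 9 of 17 purine and 11 of 17 pyrimidine genes were higher, and the 3 medians were 0.07, 0.07 and 0.08 and stayed at the 98.1, 99.9 and 99.8 percentiles, because all genes moved together.

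Genes bound by DnaA as a transcription factor had 11 of 15 members higher and a median of 0.28 at the 95.3 percentile, inside the random range. The percentile was 98.1 without genes under 300 nt. Besides nrdA and nrdB, guaB was 1.62-fold higher, whereas the aldehyde dehydrogenase gene aldA was 6.73-fold lower. Rescaling without stable RNA turned the list's median to -0.03. Replication initiation and restart genes had a median of 0.18, or -0.13 after rescaling, at the 83.5 percentile. Their 2 members at least 2-fold higher were priB, at 2.42-fold, which shares an operon with ribosomal protein genes, and fis, at 2.36-fold, which encodes a nucleoid protein abundant in fast growth. In the same list dnaT was 1.62-fold higher and cspD 1.53-fold lower. The SOS response list, which holds the genes repressed by LexA, had 23 of 32 members higher and a median of 0.17 at the 96.1 percentile, and none was 2-fold apart. The ratio of recA was 0.22 and that of lexA was -0.09, while the largest were those of yafO, ybfE, ydjM and hokE, between 0.62 and 0.72; with rescaling the list's median was -0.13. Mismatch, excision and recombination repair genes had a median of 0.03, or -0.28 after rescaling, at the 45.5 percentile. In that list the endonuclease III gene nth was 2.39-fold higher, recO 1.57-fold and recR 1.37-fold higher, and nei 1.58-fold lower. Cell division genes had a median of -0.03, or -0.34 with 2 of 21 higher after rescaling, at the 10.6 percentile, with the largest ratios at mreC (0.34), minE (-0.32), slmA (0.32) and zipA (-0.31).

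Ribosomal protein genes were higher in dnaN-E202K, by an amount that depended on scale. In the deposited values all 54 had a positive log2 ratio, the median was 0.69 (1.62-fold) and the quartiles were 0.50 and 0.80, while the random range for lists of like expression ended at 0.29. Under rescaling without stable RNA 53 were positive, with a median of 0.39. Under quantile normalization 39 of 54 were positive and the median was 0.20, at the 99.97 percentile of random lists. The largest ratios belonged to the neighbours rplI, rpsF and rpsR, at 2.51-fold, 2.40-fold and 2.35-fold, followed by rplD at 1.91-fold. Stationary phase markers had a median of -0.14 at the 2.93 percentile, just inside the random range, and left it under quantile normalization (0.51 percentile) and with the filter at 10 FPKM (2.38 percentile). It lay further inside, at the 9 percentile without genes under 300 nt and at 9.25 when the list was moved along the gene order. The general stress sigma factor gene rpoS was 2.12-fold lower, the ribosome hibernation gene rmf 1.73-fold lower, and fis, counted here too, 2.36-fold higher. The list of RpoS-dependent general stress and acid resistance genes did not follow rpoS itself: 18 of 29 were higher and the median was 0.12, at the 92.2 percentile. Rescaling without stable RNA turned it to -0.12, and scaling to the same sum of FPKM times length put the list at the 97.6 percentile, just outside the random range. In it, ecnB was 1.78-fold, osmC 1.59-fold and sodC 1.46-fold higher, and yciE was 2.09-fold lower.

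The lists of sugar uptake, TCA cycle and amino acid biosynthesis genes had medians below the random range. After rescaling without stable RNA 6 of 49, 1 of 33 and 2 of 41 of their members were higher, against 10, 9 and 14 in the deposited values. Sugar uptake and catabolite-regulated operons had 39 of 49 members lower, 10 of them at least 2-fold and none 2-fold higher, and a median of -0.37 at the 0 percentile. Of the galactose transporter genes, mglC was 7.70-fold and mglB 3.23-fold lower and mglA had 81.7 and 12.8 FPKM, and lacZ was 2.22-fold lower. TCA cycle and aerobic respiration genes had 24 of 33 members lower and a median of -0.42 at the 0 percentile. The citrate synthase gene gltA went from 589.1 to 214.1 FPKM, 2.74-fold lower, and sdhB, sucA and sdhA, of succinate dehydrogenase and 2-oxoglutarate dehydrogenase, were 2.57-fold, 2.45-fold and 2.27-fold lower. Amino acid biosynthesis genes had 27 of 41 members lower and a median of -0.22 at the 0.1 percentile. The members at least 2-fold lower were ilvG, ilvE, ilvD and leuA of branched-chain amino acid synthesis, at 2.42-fold, 2.15-fold, 2.03-fold and 2.01-fold. In the deposited values the S-adenosylmethionine synthase gene metK was 1.97-fold higher, and the histidine genes hisC, hisD and hisG had log2 ratios of 0.29, 0.27 and 0.27, near or below 0 after rescaling without stable RNA. In the tryptophanase operon, too small to rank, tnaA had 2565 and 1102 FPKM and tnaB 337.6 and 155.6, both over 2-fold lower; the leader tnaC was listed at 0 in both strains.

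Iron uptake genes, the regulon of the repressor Fur, were higher, with 35 of 37 members above 0, 5 at least 2-fold, and a median of 0.60 at the 100 percentile. Many of them were weakly expressed. The siderophore-related genes fhuF, fepD and entC were 2.17-fold, 2.12-fold and 2.06-fold higher, with 35.9, 8.25 and 4.35 FPKM in dnaN+, and the ferric citrate sigma factor gene fecI was 2.05-fold higher. After rescaling without stable RNA 31 of the 37 stayed above 0, with a median of 0.30. The list of anaerobic respiration and fermentation genes split: 8 of 31 were at least 2-fold higher, all others were less than 2-fold apart, and the median was 0.18 at the 82.7 percentile. The higher ones were the nar genes, among them narJ at 2.47-fold, with napF, ackA and pta, while fumarate reductase genes frdA to frdD had log2 ratios from -0.30 to -0.20. Rescaling turned that list's median to -0.09.

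**Figure D2:**
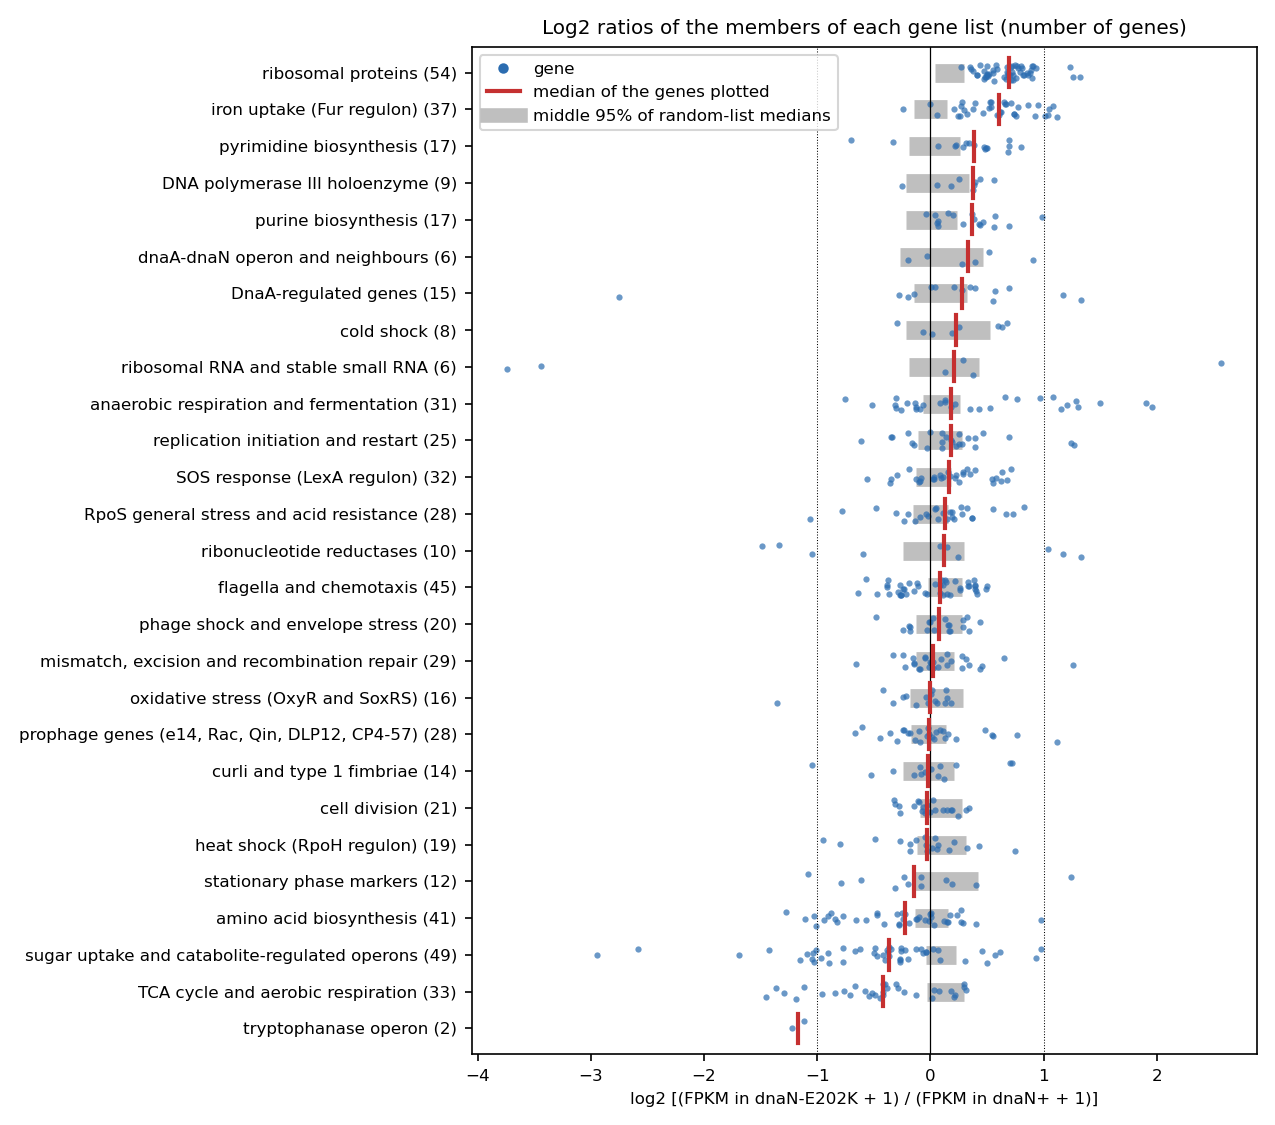
Log2 ratio of dnaN-E202K over dnaN+ for each measured gene (dots) in the 27 lists, with the median of the genes plotted (red bar) and the middle range of medians of random lists (grey); genes listed at 0 in 1 strain are left out. Ribosomal protein and iron uptake genes lie to the right, and sugar uptake, TCA cycle and tryptophanase genes to the left.

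The other lists had medians inside the random range, except that of ribosomal and stable RNA. Heat shock genes had a median of -0.03, or -0.34 with 3 of 19 higher after rescaling without stable RNA, at the 9.49 percentile, with ibpA and ibpB 1.93-fold and 1.74-fold lower, htpX 1.40-fold lower and rpoD 1.68-fold higher. Cold shock genes had a median of 0.22, or -0.08 after rescaling without stable RNA and -0.03 under quantile normalization, at the 66.0 percentile, with deaD, cspI and rbfA 1.60-fold, 1.55-fold and 1.51-fold higher and cspE 1.23-fold lower. Flagella and chemotaxis genes, with 24 of 45 higher, had a median of 0.09, or -0.22 after rescaling and -0.02 under quantile normalization, at the 24.0 percentile; cheB and cheR were 1.56-fold and 1.48-fold lower, and fliK and fliN 1.41-fold higher. Oxidative stress genes, 8 of 16 higher, had a median of 0.00 at the 30.9 percentile, and after rescaling 0 of 16 were higher and the median was -0.31; the 1 member 2-fold apart was fumC, a fumarase gene, at 2.56-fold lower, followed by fpr and katG at 1.33-fold and 1.26-fold lower. Curli and type 1 fimbriae genes had a median of -0.02, or -0.25 with 2 of 14 higher after rescaling, at the 47.3 percentile, where the recombinase gene fimB was 2.06-fold lower and the fimbrial subunit gene fimA had 416.7 and 435.7 FPKM. Phage shock and envelope stress genes had a median of 0.08, or -0.22 after rescaling, at the 50.3 percentile, with pspD 1.39-fold lower and rseC 1.36-fold higher. Prophage genes had a median of 0.02, or -0.24 after rescaling, at the 62.6 percentile; of their 4 members over 2-fold higher, kilR, dicB and ydfD were listed at 0 in dnaN+ and alpA had 1.49 and 4.39 FPKM. At 10 FPKM or more in that list, nmpC was 1.52-fold lower and racR 1.47-fold higher.

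Ribosomal RNA, which the library preparation removes, left uneven values. The 5S genes summed to 45636 FPKM in dnaN+ and 3499 in dnaN-E202K, all of it at 2 of 8 copies. The 16S genes were listed at 0 in dnaN+ at all 7 copies and at 5 copies above 0 in dnaN-E202K, among them rrsG at 1281, rrsC at 994.9, rrsA at 923.3 and rrsD at 766.6 FPKM. The 23S genes were listed at 0 in both. Near-identical copies share reads, so the value of a single copy is uncertain, and the list's median, 2.57 with the genes listed at 0 and 0.21 without them, is not a measure of ribosomal RNA content; its place among random lists went from the 100 to the 44.5 percentile with no filter. Of the stable small RNAs, the short ffs RNA had 290.2 and 1729 FPKM, whereas ssrA, ssrS and rnpB had log2 ratios of 0.29, 0.38 and 0.13.

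The clamp acts in replication, and gene dosage in growing cells falls from the origin to the terminus, so the ratios were also set against position. Over 4030 genes the rank correlation of the log2 ratio with the number of genes from oriC was 0.12, across genes that are not independent replicates. Of the circular shifts, 23.5% gave a correlation as large in size, and the middle range of the shifts ran from -0.13 to 0.13, so the trend did not exceed that of ratios moved at random along the chromosome. The median log2 ratio was -0.05 among the 804 genes nearest to oriC, 0.01, 0.05 and 0.11 in the next 3 groups, and 0.06 among the 788 farthest.

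**Figure D3:**
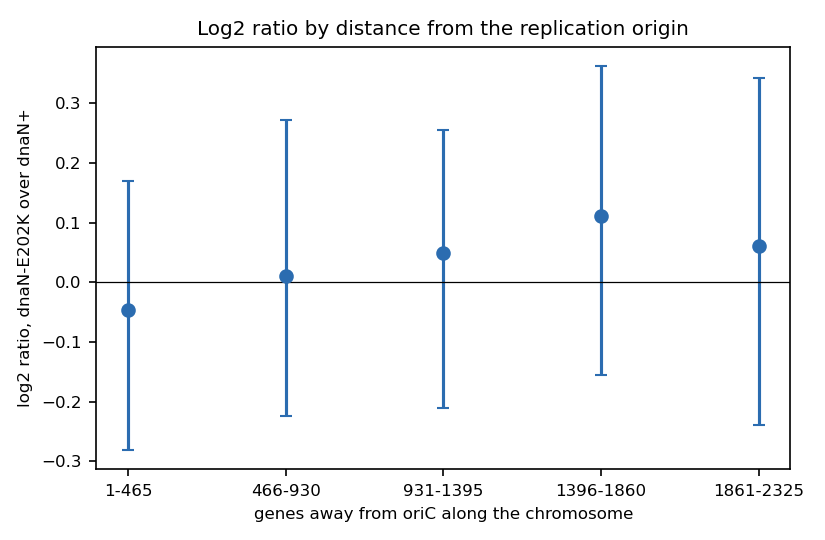
Median log2 ratio of dnaN-E202K over dnaN+ (points) with the quartiles of the genes (bars) in 5 groups by the number of genes from oriC. The medians run from -0.05 to 0.11 and lie within the quartiles of every other group.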

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

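No paired analysis was possible because the deposited table holds 1 value per strain and carries no replicate numbers. For the same reason the planned linear-model settings (trend, robust fit, adjusted p with a fold minimum), rotation tests, sets with an estimated correlation, count models and the leaving out of single samples were not run. With no replicate spread, a ratio was treated as kept when it moved by at most 0.1 on the log2 scale and a count when it stayed within 1.5 times. Pseudocounts of 0.1 and 5 FPKM, no filter, a filter at 10 FPKM, median scaling, quantile normalization and leaving out genes under 300 nt kept the counts of genes 2-fold apart within 1.5 times, the 3 clamp and reductase ratios and the origin trend (0.11 to 0.14). Quantile normalization moved the ratios of 11 other named genes by over 0.1, lowered the median of the ribosomal protein genes to 0.20 and that of the dnaA-dnaN list to 0.11, and turned that of cold shock genes to -0.03 and that of flagella genes to -0.02; the cause was not tested. The 2 settings that moved the counts and the dnaN, nrdA and nrdB ratios are single factors that lower all dnaN-E202K values. Neither factor is independent of the results, because abundant genes weigh heavily in the sums. The ribosomal protein gene rpmJ alone had 258951 FPKM in dnaN+ and 364905 in dnaN-E202K, of sums without stable RNA of 2.04e+06 and 2.52e+06. A rise of such genes by itself lowers all other dnaN-E202K values under that rescaling. Rescaling to the same sum without stable RNA gave 25 genes higher and 198 lower, with log2 ratios of 0.085 for dnaN, 1.03 for nrdA and 0.86 for nrdB. Scaling to the same sum of FPKM times length, chosen after seeing the data, gave 37 higher and 176 lower, with 0.15 for dnaN, 1.09 for nrdA and 0.93 for nrdB. Of the 121 named genes, 5 took the other sign under the former (dnaA, hda, fimC, fimI and fimA) and 3 under the latter. The number of lists outside the random range was 8 to 10 under all these settings against 9; rescaling without stable RNA gives no value for the list of ribosomal and stable RNA, and all 26 lists kept their place when the random lists were the same list moved along the gene order. The pseudocount of 5 moved the ratios of 39 of 118 other named genes by over 0.1, and 1 of 0.1 FPKM moved 14. Unknown depth leaves the counting error of genes near 1 FPKM open.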

Other observations

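The lists and tests in this part were all chosen after the data had been seen. Because the gene lists were compiled with the values known and include genes named above as lowest or highest, their counts describe those genes and do not test the regulators. Of 50 genes in operons that need the catabolite activator protein CRP, 42 were lower in dnaN-E202K, 26 of them at least 2-fold, with a median log2 ratio of -1.02; the sugar uptake list fixed beforehand had -0.37. Of the 50, 34 are also in the lists of the report. Besides the acetate and galactose genes, the D-alanine catabolism genes dadX and dadA were 5.97-fold and 4.64-fold lower, and the sialic acid lyase gene nanA had 1722 FPKM in dnaN+ and 773.9 in dnaN-E202K. The ribose transporter gene rbsB, with a log2 ratio of 0.57, was among the 8 members of the CRP list with higher values. Aerobic operons repressed by ArcA had 32 of 37 members lower, 15 at least 2-fold, and a median of -0.81, and 23 of them are in the lists of the report. Among them the glyoxylate shunt genes aceB and aceA were 4.03-fold and 3.71-fold lower, while the cytochrome bo genes cyoA to cyoE, its 5 higher members, had ratios from 0.02 to 0.30, which lie near or below 0 after rescaling without stable RNA. The dipeptide transporter genes dppB, dppC and dppD were 3.18-fold, 3.95-fold and 3.52-fold lower, and the transporter gene yhjX was 7.19-fold lower.

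Several operons outside the fixed lists were higher. The nickel transporter genes nikA and nikE were 2.31-fold and 2.21-fold higher, the pyruvate dehydrogenase operon genes pdhR and aceF 2.06-fold and 2.49-fold, the NADH dehydrogenase gene ndh 2.12-fold with its neighbour ycfJ at 3.19-fold, and the fatty acid transporter gene fadL 2.23-fold. In the rsx operon, which ends at nth, ratios stood at 0.44, 0.38 and 0.59 for rsxA, rsxB and rsxC and at 1.10, 1.11 and 1.25 for rsxD, rsxG and rsxE. A further list was compiled as growth genes activated by Fis, with fis itself in it. Whether Fis activates each member was not examined here. All 13 members were higher in the deposited values, with a median of 0.47. That median lay at the 96.8 percentile, inside the random range, and at 99.7 when the list was moved along the gene order. The ratios of rpsB, tsf, fusA and tufA, from 0.22 to 0.30, lie near or below 0 after rescaling without stable RNA. Of the 13, 5 are in the lists of the report, among them the ribosomal protein genes rpsA, rpsB, rplJ and rplL. A list compiled as oxygen-repressed operons that nitrate does not hold down had 11 of 13 members higher and a median of 0.30. The rescaling, which moved the median of all genes by -0.29, brings that median near 0. Its 4 members at least 2-fold higher were the nickel transporter genes nikA, nikB, nikC and nikE. Whether nitrate holds that operon down was not examined here, so its place in this list is uncertain. Oxygen-repressed operons that nitrate does hold down, ydh among them, had 19 of 28 members lower and a median of -0.13. Neighbouring genes had like ratios: over 3626 adjacent pairs the rank correlation was 0.54, against -0.03 to 0.03 in 1000 shuffles, and the median gap between neighbours was 0.21 on the log2 scale against 0.40 for shuffled pairs.

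The ribosomal protein genes were higher by a median of 0.69. Gene length argues against a bias of short genes, as other coding genes of the same lengths had a median of 0.056, below the lower quartile of the ribosomal protein genes at 0.50. For expression level, the other coding genes nearest in FPKM had a median of 0.23, also below that quartile. This cannot decide an effect at the top of the range. The ribosomal protein gene rpmJ was the most abundant coding transcript, so the genes compared with it lie below it in FPKM. An effect of expression level stays open, and the median of 0.23 lies above the 0.03 of all genes. Quantile normalization lowered the median of the ribosomal protein genes to 0.20 with 39 of 54 higher. It cannot decide this, because it shrinks any common rise of the most abundant genes, whatever the cause. A dnaN-E202K culture sampled further from stationary phase is a candidate explanation that stays open: rpoS and rmf were lower and fis higher, but the RpoS-dependent list, which it predicts to be low, lay at the 92.2 percentile, inside the random range. The allele and the state of the cultures cannot be told apart for these genes, because no culture densities or separate sample values were used here.

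The higher nrdA and nrdB values were local to that operon. The 20 genes on both sides had a median log2 ratio of 0.094 (SD 0.26), far below nrdB at 1.17, which argues against a change in copy number of the region. Altered DnaA-dependent regulation is a hypothesis that the other 13 DnaA-regulated genes do not decide, since their median of 0.21 lay at the 84.4 percentile, within the random range, and DnaA represses some targets and activates others. An effect of growth state on the operon and an effect of the allele were not tested.

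Nitrate-activated operons were higher, with 17 of 18 members above 0 and a median of 0.84, while 6 genes of the ydh operon were 2.93-fold to 8.08-fold lower. The rise was not uniform. The 8 members at least 2-fold higher were nar genes, fdnG, napF and napD, whereas nirB, nirD and nirC had log2 ratios of 0.35, 0.18 and -0.31. Less oxygen in the dnaN-E202K culture would by itself raise operons such as frd, dms, nrf, hyb and that of focA and pflB. These operons had a median of -0.079 (SD 0.36) without ydh and tor, which argues against less oxygen as the only difference. The set was not uniform: pflB and focA had log2 ratios of 0.97 and 0.53, while dcuB and adhE had -0.75 and -0.51. Less oxygen stays open together with nitrate, which holds those operons down. TCA cycle and aerobic respiration genes were lower, with a median of -0.42, but that list is mixed and does not decide it. Its cyoA to cyoE genes, which ArcA represses, were not lower, with ratios from 0.02 to 0.30. Its oxygen-repressed genes cydA and cydB had 0.30 and 0.32. Of the operons that ArcA represses, 32 of 37 members were lower. More nitrate or nitrite signal may be involved but was not decided. The operons it holds down lay at the 0.94 percentile of random lists, but at the 7.96 percentile, inside the random range, when the list was moved along the gene order. The low ydh genes were also part of what was seen first, and without ydh and tor the rest lay at the 3.77 percentile, inside the random range. An effect of the allele itself was not tested, and neither oxygen nor nitrate levels are given in the sources used here.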
